A study of Mus musculus with 1152 samples.

How the data were processed

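RNA was measured in single cells of the adult mouse brain with SMART-seq2, a plate method that amplifies full-length cDNA from a single cell per well. Per the labels, fluorescent cells were sorted from 2 mouse lines of the C57BL/6 strain. In Pdgfra-H2BGFP mice a nuclear green fluorescent protein follows Pdgfra, the gene of the alpha receptor for platelet-derived growth factor. In the line written Tagl-CREERT2;Ai14 in the labels, a tamoxifen-dependent recombinase switches on a red fluorescent protein. Animals of both sexes were used, the brain was digested, and vascular fragments were taken with magnetic beads carrying an antibody against CD31, an endothelial surface protein, before a further digestion and the sort.

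The values used are counts of reads per gene as deposited, whole numbers that were not normalized. The submitters' processing notes name TopHat2 2.1.1, SAMtools 0.1.18 and featureCounts of Subread 1.4.6-p5, with the mouse builds GRCm38 and mm10. The gene annotation, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical paralogs can therefore be shared between genes, and values of such genes are uncertain. The libraries carry no molecular identifiers, so reads copied by PCR are not independent molecules and every interval below covers counting error only.

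The table held 46517 genes and 1152 wells in 3 sets of 384 wells, named 1025s_182s, 600s_182s and 613s in the well names. The labels tie no well to a mouse line, animal or plate, and their numbered titles match no well name, so all wells were treated as 1 sample. Cells are not replicates, and no test, p-value or standard error was made from them. Every comparison lacks a replicate check. No transcript of a reporter was found among the gene names, so cells were not assigned to a line. Symbols were matched to the GENCODE vM21 annotation of GRCm38, in which 42052 of the 46517 (90.4%) were found, and coordinates come from that match.

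Wells with at least 50000 reads and at least 1000 genes were kept as cells. This left 857 cells and removed 295 wells, all 295 for too few reads and 3 also for too few genes. Kept cells had 50002 to 1451280 reads (median 279874) and a median of 6694 genes. Counts were scaled by the total of each cell to CPM (counts per 1e6 reads) and taken as log2(CPM + 1). Genes were divided by a hash of their symbol into a group for clustering and a group held out of it. All 363 genes of the fixed lists, of which 362 were in the table (Vegfd was not), were moved to the held-out group. This gave 23085 genes eligible for clustering and 23432 held out. The 2000 most variable eligible genes, 20 principal components, 15 nearest neighbours and Leiden clustering at resolution 0.5 (1 for sub-clusters, seed 1) gave 12 clusters.

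Clusters were named from held-out markers of 16 cell types, and called "like" that type only where at least 3 of its markers were detected at 10 CPM and the leading genes did not go against the name. A cluster whose median depth was under 1 in 3 of the median of all cells, with no marker of the type among its 10 leading genes, stayed unnamed. This depth clause was added to the planned naming rule. It does not cover the astrocyte name for clusters 3 and 9, which had Gfap and Aldoc among these genes. There the neuronal genes beside them went against that name. The lists, markers, filters, comparisons and the rule for named genes were set before the data were examined, while the names of the clusters were given after. No caller for droplet doublets was run, because cells were sorted into wells. A cell was called mixed when it had at least 3 markers at 20 CPM of each of 2 lineages, and mixed cells were kept in the main results.

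Classes were compared by the ratio of CPM of summed counts, with 1 CPM added to each side, on the log2 scale. A gene was called higher or lower where this ratio was at least 2 and the higher class had at least 10 CPM. These calls describe size only. CPM values have exact Poisson 95% intervals and shares of cells exact Clopper-Pearson 95% intervals. To compare shares of cells with reads, each cell was thinned to 50000 reads, a depth that every kept cell reached, and 1 read counted as detection. A list was summarised by the median log2 ratio of its members with at least 10 CPM in either class. Its interval is the order-statistic 95% interval of the median over members, and its percentile comes from 10000 random lists of equal size matched on expression in 20 bins, as a description of these cells. Values within a set of wells were computed where both classes had at least 5 cells there. A class with under 20 cells was only counted.

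The lists covered the basement membrane, interstitial matrix, contractile apparatus, ion channels and vasoactive receptors, solute carriers and ABC transporters, retinoid handling, BMP and TGF-beta signalling, Wnt signalling, cytokines and growth factors, cell junctions, the dissociation and stress response, and proliferation. Lists of 5 meningeal layers (perivascular fibroblast, pia, arachnoid, arachnoid barrier, and dura with its border) described sub-clusters, and a sex-linked list served to count cells. The genes named in a comparison are the 10 with the largest ratio in each direction among held-out genes, or 8 in the higher direction only for a sub-cluster or for a class against all remaining cells. They needed at least 50 CPM in the higher class and reads in at least 50% of its thinned cells, and predicted genes, mitochondrial genes and genes of ribosomal proteins were left out. The rule also admits the 2 highest and 2 lowest members of each list, of which part are printed (some genes are not reported here), and always Pdgfra, Tagln and Pdgfrb. Leading genes of clusters, the markers that place cells in clusters and the genes of the closing part other than list members were chosen after their values were seen.

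The median log2 ratio over all genes at 10 CPM was −0.17 for fibroblast-like against OPC-like cells, −0.11 for COP-like cells and −0.42 for oligodendrocyte-like cells. It was 0.07, −0.35 and −0.09 for fibroblast sub-clusters 1, 2 and 3. Ratios are printed on the scale of total counts, and the percentiles of the lists are relative to matched genes and so to this shift. Genes without reads in a class have a bound of 3 counts. With such members placed at that bound, 1 of 87 list medians moved by over 0.1, by 0.20.

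The steps were tested on simulated data drawn from the means of the real classes. The clustering returned 857 of 857 simulated cells to the cluster of their own kind, using 23085 genes. For the clustering, each simulated cell came from the mean of its own cluster. For the ratios, both classes came from the mean of the second class, with 200 genes changed by known folds in the first. The spread was independent between genes. Mixed cells and values carried by a few cells were thus not simulated. The recovery below and above checks the steps, not how well the real cells separate. Over 46517 genes of the simulated fibroblast-like against OPC-like comparison, the size rule found 100 of 100 genes changed 4-fold, 100 of 100 changed 8-fold and 0 of 10787 unchanged genes. For sub-cluster 2 it found 99 of 100 and 100 of 100, and called 40 of 10279 unchanged genes (0.389%). Of 100 simulated lists without a change, 8 and 2 lay outside the central 95% of random lists in these 2 comparisons.

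Alternatives changed the cell filter, the genes used for clustering, the resolution, the number of principal components, the treatment of mixed cells, the weight of each cell, the scaling (TMM factors of edgeR, size factors of DESeq2), the pseudocount, the list filter, the thinning and the detection limit. The closing part gives their effect. The planned comparisons of fibroblast-like with mural-like cells and of smooth muscle-like with pericyte-like cells, and the sub-clusters of mural cells, were not made because no cluster was mural-like. Tools were Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.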

Results

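The data are read counts of 1152 wells that received fluorescent cells of the adult mouse brain, in 3 sets of 384 wells. The mouse lines mark cells that use Pdgfra, a receptor gene of fibroblasts and of oligodendrocyte precursors, and cells of the line named for Tagl. Of the wells, 857 passed the filter, with 239 cells in set 1025s_182s, 349 in 600s_182s and 269 in 613s. Their median depths were 303889, 279962 and 250526 reads, and all kept cells together held 286470775 reads. Median numbers of genes were less alike, at 4017, 7519 and 6726 in the same order. The shares of thinned cells below are evened for reads only. The labels do not say which well belongs to which line, so the comparisons below are between classes of cells defined by their own transcripts, in 1 sample without replicates.

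Cells of the oligodendrocyte lineage, which forms myelin, were the largest group in each set, but most of the cells in only 1 of the 3. Oligodendrocyte precursor-like (OPC-like) cells made up 250 of the 857 cells (29.2%, 95% interval 26.1 to 32.3), and oligodendrocyte-like cells 209 (24.4%, 21.5 to 27.4). Cells like committed oligodendrocyte precursors (COP-like), the stage between them, numbered 79 (9.22%, 7.37 to 11.4), so that the lineage held 538 cells (62.8%, 59.4 to 66.0). It made up 90.3% of the cells of 600s_182s, but 41.0% of 1025s_182s and 46.5% of 613s, and without 600s_182s the shares were 43.9% for the lineage, 11.2% for OPC-like and 2.36% for COP-like cells. Fibroblast-like cells numbered 102 (11.9%, 9.81 to 14.3), and 14 cells resembled the epithelium of the choroid plexus, which makes cerebrospinal fluid. With cells mixed at 20 CPM left out, fibroblast-like cells were only 9 of 392 (2.30%), and COP-like cells rose to 16.6%, as they did to 16.0% at the lower resolution. These shares follow the sort for fluorescence and the capture of vascular fragments, and are not shares of brain cells.

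The classes were unevenly spread over the sets. OPC-like cells numbered 20 in 1025s_182s, 193 in 600s_182s and 37 in 613s, COP-like cells 2, 67 and 10, oligodendrocyte-like cells 76, 55 and 78, and fibroblast-like cells 49, 25 and 28. Of the 3 OPC-like clusters, cluster 1 took 175 of its 180 cells from 600s_182s, cluster 8 took 19 and 31 of its 53 from 1025s_182s and 613s, and cluster 11, with 15 of its 17 cells from 600s_182s and 0 from 1025s_182s, was led by the cell cycle genes Top2a, Cdk1 and Aurkb. The oligodendrocyte-like cells likewise lay in cluster 2, with 151 cells and none from 600s_182s, and in cluster 7, with 55 of 58 cells from that set. In these clusters the set and the kind of cell are not separable.

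**Figure D1:**
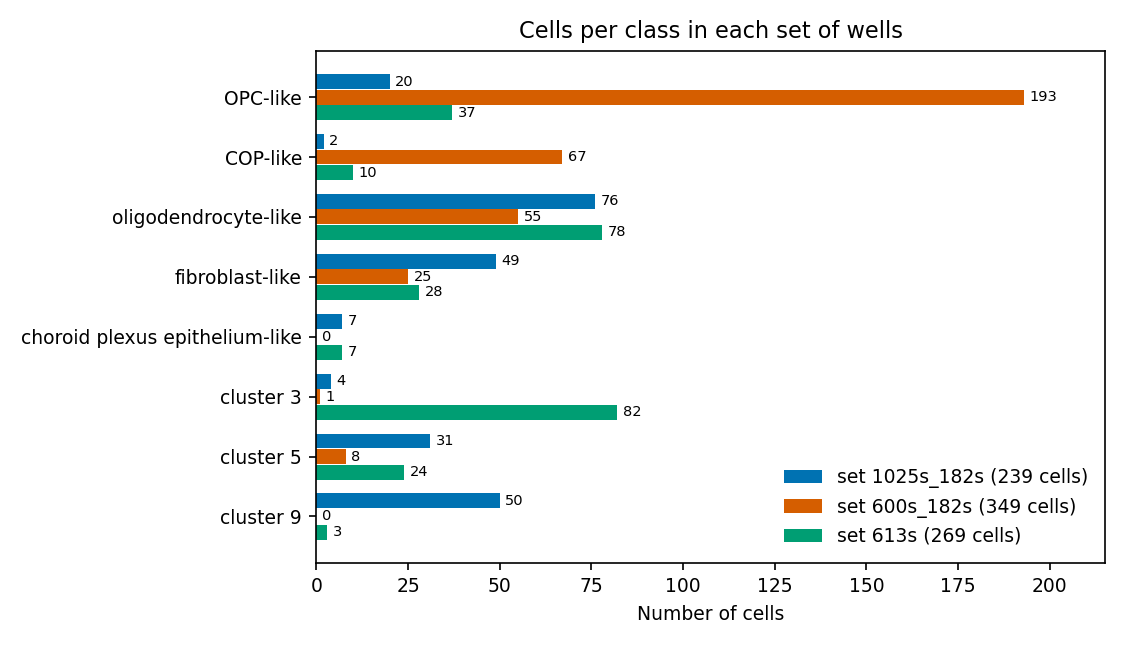
Bars give the number of cells (horizontal axis) in each class or unnamed cluster (vertical axis), with a bar for each of the 3 sets of wells. Set 600s_182s held 193 of the 250 OPC-like cells and 67 of the 79 COP-like cells, and set 1025s_182s held 49 of the 102 fibroblast-like cells.

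Clusters 3, 5 and 9 stayed unnamed. Cluster 5, with 63 cells (7.35%), joined markers of vessel cells and of immune cells of the brain. Its CPM was 1170 for Pecam1 and 2327 for Cldn5, both of endothelial cells, 830 for the pericyte gene Rgs5 and 1028 for the microglial gene Csf1r. It also carried all 5 listed erythrocyte genes above 10 CPM, such as Hbb-bs at 97.9 CPM, and 2 of 5 lymphocyte and 2 of 5 neutrophil or monocyte markers. At 200 CPM, 58 of its cells had at least 3 endothelial markers, 19 had 3 pericyte markers, 12 had 3 smooth muscle markers, 33 had 3 microglial markers and 1 had 3 markers of perivascular macrophages. Both endothelial and mural markers were found in 23 cells, mural markers alone in 0. Cluster 3 (87 cells, 82 of them from 613s) was led by Gfap, an astrocyte filament gene, with the neuronal genes Adcy1 and Ddn. Cluster 9 (53 cells, 50 from 1025s_182s) was led by Nrsn1 and Kif5a, with the astrocyte marker Aldoc among its 10 leading genes. Their median depths were 88314 and 84423 reads.

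Many cells carried markers of more than 1 lineage. At 20 CPM, 465 of 857 cells (54.3%, 50.9 to 57.6) were mixed, among them 91.2% of fibroblast-like and 17.7% of COP-like cells. Without the oligodendrocyte lineage 258 cells (30.1%, 27.0 to 33.3) were. At 200 CPM, 183 cells (21.4%) remained mixed, among them 48 of the 102 fibroblast-like cells. Of these 102, 42 had at least 3 markers of the oligodendrocyte lineage at that level and 12 had 3 endothelial markers. Over all cells at 20 CPM, at least 3 markers were found in 167 cells for astrocytes, 73 for neurons, 7 for ependymal cells and 38 for the choroid plexus, and no cluster took a name from astrocytes, neurons or ependymal cells.

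Pdgfra (GRCm38, chromosome 5, 75152292 to 75198215, plus strand) was highest in OPC-like cells, at 1208 CPM (1200 to 1216), with reads in 98.8% of thinned cells. Fibroblast-like cells had 398 CPM (391 to 405) and 91.2%, and COP-like and oligodendrocyte-like cells 16.6 and 16.8 CPM, with 55.7% and 32.1%. Pdgfrb, the beta receptor of the same ligand family and a gene of mural cells and fibroblasts (chromosome 18, 61045150 to 61085061, plus strand), reached 805 CPM (795 to 815) in fibroblast-like cells, in 80.4% of them. OPC-like cells, which lack this receptor in textbook accounts, had 2.65 CPM and reads in 12.0%. Both classes were thinned alike, from median depths of 237029 and 259194 reads. In the Pdgfra-H2BGFP line the sort acted on a reporter of Pdgfra. The presence of this gene may therefore be set in part by the gate, which is not described.

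Tagln, which encodes the smooth muscle protein transgelin (chromosome 9, 45929619 to 45936058, minus strand), was low in most cells. It had 27.5 CPM over all cells and 220 CPM (214 to 226) in cluster 5, where 27 of 63 thinned cells (42.9%) held reads. Fibroblast-like cells had 53.5 CPM (50.9 to 56.2, an interval for the counting of reads only) and 12.7%, but their median cell was at 0 CPM and only 4 of the 102 were over 100 CPM, 3 of them over 1000, so a few cells carry this value. In cluster 5 the median cell was at 6.00 CPM and 16 cells were over 100. OPC-like cells had 1.41 CPM and 5.20%. The smooth muscle genes Acta2 and Myh11 stood at 736 and 223 CPM in cluster 5. At least 3 smooth muscle markers at 20 CPM were found in 37 cells, 20 of them in cluster 5, and they formed no cluster of their own.

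Fibroblast-like and OPC-like cells, the 2 kinds of brain cell known to use Pdgfra, were compared first. Fibroblast-like cells were higher for Dpep1, Coch, Cped1, Inmt, Tgfbi and 5 further genes, each by a log2 ratio of at least 7.79. Dpep1, a membrane dipeptidase (chromosome 8, 123186242 to 123201812, plus strand), had 1064 CPM (1053 to 1076) against 1.71 (1.43 to 2.03), a log2 ratio of 8.62, with reads in 59.8% (49.6 to 69.4) against 5.20% of thinned cells. The secreted proteins Coch (8.34) and Tgfbi (8.06), the methyltransferase gene Inmt (8.15), Cped1 (8.15), the scavenger receptor Colec12 (7.96), the laminin gene Lama2 (7.82), the proteoglycan gene Lum (7.80), Pdgfrb (7.79) and the mesenchymal transcription factor Tcf21 (7.79) followed on the log2 scale.

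OPC-like cells were higher for Lhfpl3, Matn4, Cspg5, Ptprz1 and 6 further genes. Cspg5, a brain chondroitin sulphate proteoglycan (chromosome 9, 110243783 to 110262576, plus strand), had 1515 CPM (1507 to 1524) against 12.2 CPM in fibroblast-like cells, a log2 ratio of −6.85, with reads in 99.6% against 38.2% of thinned cells. Log2 ratios were −6.89 for Lhfpl3, −6.87 for the matrilin gene Matn4, −6.83 for the receptor phosphatase Ptprz1, −6.70 for the proteoglycan neurocan (Ncan) and −6.70 for the semaphorin Sema5b. They were −6.69 for Megf11, −6.68 for the neurexophilin Nxph1, −6.66 for the Notch ligand Dll3 and −6.63 for the astrotactin Astn1. Lum, Lhfpl3, Cspg5 and Ptprz1 are among the markers that named the classes. Within sets, these 10 genes had ratios of −4.40 to −4.79 in 600s_182s, closer to 0 than in both other sets. Pdgfra itself was lower in fibroblast-like cells, at −1.60, and at −1.35, −0.78 and −1.71 within 1025s_182s, 600s_182s and 613s. The ratio of Tagln was 4.50 overall but 5.78, 0.11 and −0.98 within these sets.

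The matrix lists stood highest. Of 24 measured interstitial matrix genes 23 were higher in fibroblast-like cells and 0 lower, with a median log2 ratio of 5.74 (3.45 to 6.64), and with 6.72, 5.51 and 5.58 within the sets. These values within sets compare different fibroblasts, since 23 of the 25 fibroblast-like cells of 600s_182s lay in sub-cluster 2 below, against 7 of 49 in 1025s_182s and 1 of 28 in 613s. Osteoglycin (Ogn) at 7.77 and Prelp at 7.39, both small leucine-rich repeat proteins, led, and elastin (Eln) stood at −0.18. The fibulin gene Fbln2 was at 2.00 overall and at −0.03, 4.89 and −1.75 within the sets. Of 17 basement membrane genes 16 were higher and 1 lower, with a median of 5.44 (3.46 to 6.51), and with 6.10, 6.63 and 5.91 within the sets. Lama2 and Lamc3 (7.75), both laminin chains, were highest, and agrin (Agrn), which binds laminin, was lower at −1.80.

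Most signalling and transport lists were also higher in fibroblast-like cells. Each list is a small fixed choice of genes, so its values do not speak for a whole family or pathway. Medians within 1025s_182s, 600s_182s and 613s follow the pooled median, which weighs the sets by their unequal numbers of cells and can lie outside them. Of 26 transporters 19 were higher and 3 lower (median 3.66, and 4.33, 3.36 and 4.04), with Abca9 at 7.43, the cystine exchanger Slc7a11 at 6.87 and Slc41a2, a magnesium transporter, at −3.24. Of 12 genes of retinoid handling 11 were higher and 0 lower (3.43, and 5.28, 3.14 and 4.61), with the retinaldehyde dehydrogenase Aldh1a2 at 6.71 in 25.5% of the cells, the reductase Dhrs3 at 6.43 and Aldh1a1 at 0.81. Of 27 cytokines and growth factors 22 were higher and 2 lower (3.87, and 5.23, 4.21 and 4.27), led by the chemokine gene Cxcl12 at 7.64. Igfbp3 stood at −1.29, with −3.92, −4.37 and 1.05 within the sets. Of 10 Wnt genes 7 were higher and 1 lower (3.52, −0.03 to 6.62, and 4.00, 2.70 and 4.43), with the ligands Wnt2 at 7.15 in 22.5% of the cells and Wnt5a at 6.62, the inhibitor gene Frzb at −0.03 and Sfrp4 at −1.34. Of 15 BMP and TGF-beta genes 11 were higher and 0 lower after pooling (2.49), but the medians within the sets were 5.05, 2.84 and 3.70, with 1, 2 and 3 lower members. This list had the pathway inhibitor Smad6 at 5.98, Id3 at 5.88 and Bmp7 at −0.48.

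Of 14 contractile genes 13 were higher and 0 lower (3.23, and 4.01, 3.08 and 2.97), with myosin light chain kinase (Mylk) at 6.03, Myl9 at 5.96 and the tropomyosin Tpm1 at −0.60. Markers of vessel cells moved with this list, at 87.3 against 4.21 CPM for Pecam1, 252 against 17.8 for Cldn5, 31.3 against 2.06 for Rgs5 and 104 against 8.94 for Acta2, and Acta2 was at 2.23 CPM in the median fibroblast-like cell and over 100 CPM in 8 of 102, so RNA of vessel cells in some wells is not excluded as a source. Of 12 channels and vasoactive receptors 8 were higher and 4 lower (2.17, −3.46 to 3.36, and 1.62, 2.00 and 3.00). The neuropeptide Y receptor Npy1r stood at 5.18 with reads in 15.7% of fibroblast-like cells, the adenosine receptor Adora2a at 3.77, and the endothelin receptor Ednrb at −6.36. Of 15 junction genes 9 were higher and 4 lower (2.83, −1.34 to 4.21, and 3.27, 0.57 and 3.04), with the connexins Gjb2 at 6.43 and Gjb6 at 4.96 against Jam2 at −2.21 and Cldn10 at −2.70. Genes of the dissociation and stress response were higher in 13 of 17 cases and lower in 1 (2.97, and 2.96, 2.21 and 2.78), led by Zfp36 at 5.69 and Atf3 at 4.42, with the heat shock gene Hsph1 at −1.22. Of 11 proliferation genes 0 were higher and 9 lower (−4.72, −4.30, −3.56 and −3.34 within the sets, and −2.49 without the cycling cluster 11), with Top2a at −5.51, Ccnb1 at −5.46 and Pcna at −0.38. Every list lay at the 99.91 percentile of random lists or above, except proliferation at 0.

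**Figure D2:**
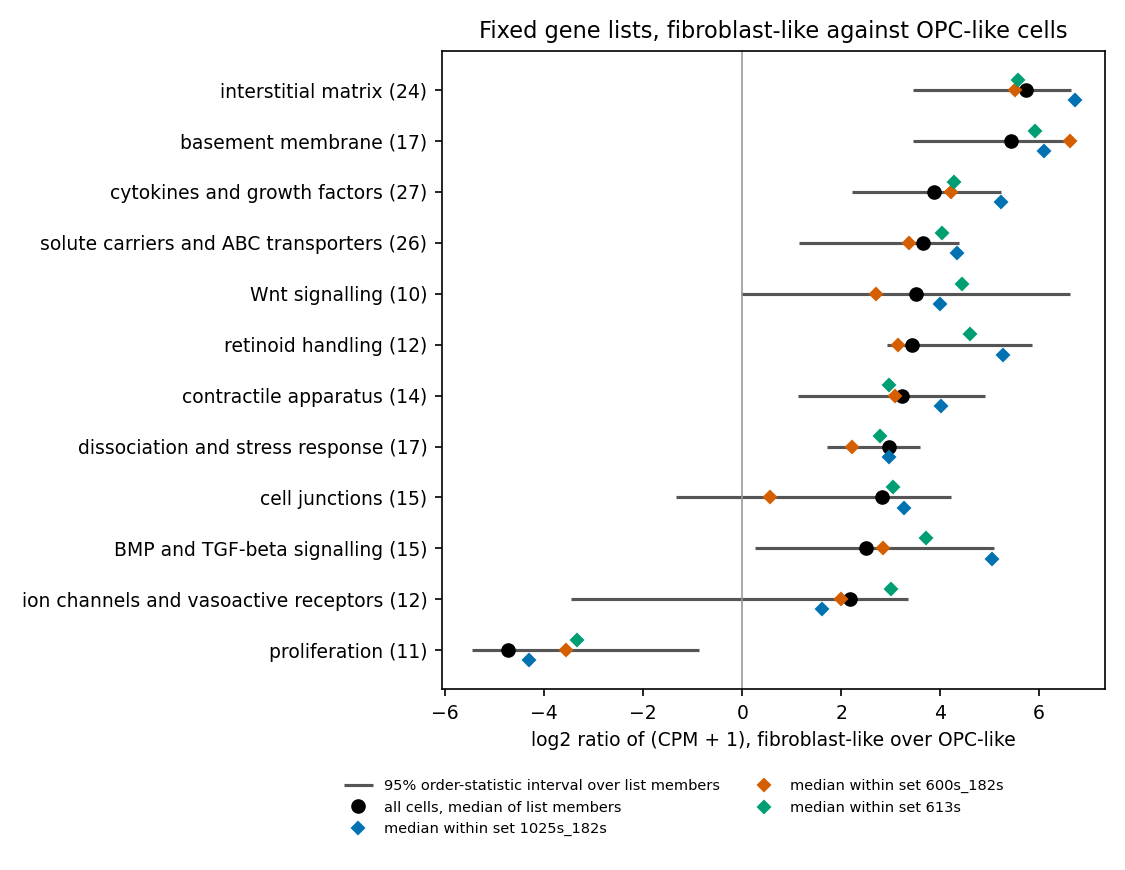
Points give the median log2 ratio (CPM + 1) of fibroblast-like over OPC-like cells (horizontal axis) for the 12 gene lists (vertical axis), with the order-statistic 95% interval over members and smaller symbols for the medians within each set of wells. Interstitial matrix (5.74) and basement membrane (5.44) lie highest and proliferation (−4.72) lies lowest.

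COP-like cells were set against the 778 remaining cells. They were higher for Enpp6, Pycr1, Gng4 and Bmp4, each by a log2 ratio of at least 4.70. Enpp6, a choline phosphodiesterase of newly forming oligodendrocytes (chromosome 8, 46986887 to 47096762, plus strand), had 1756 CPM (1743 to 1768) against 54.7, with reads in 100% against 46.7% of thinned cells and a log2 ratio of 4.98 (4.53 within 600s_182s, 5.98 within 613s). The proline synthesis gene Pycr1 stood at 4.75, the G protein subunit Gng4 at 4.74, the ligand Bmp4 at 4.70, the kinase Fyn at 4.53, Sema4a at 4.12, the kinesin Kif19a at 3.97 and the serine hydroxymethyltransferase Shmt1 at 3.96. Enpp6 and Fyn are naming markers. Set 1025s_182s held only 2 COP-like cells and gives no value.

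Among list members, the growth factor Pdgfa (2.50, 247 against 42.7 CPM), the endothelin receptor Ednra (2.02), the sulphate transporter Slc26a2 (1.51), the junction gene Jam2 (1.42) and the Wnt target Axin2 (1.02) were higher in COP-like cells. Pdgfra (−4.66), Tagln (−4.55) and Pdgfrb (−5.69) were lower. The remaining cells include the fibroblast-like and vascular cells, and all 12 list medians were below 0, at the 3.54 percentile or lower. They were below 0 within 600s_182s and 613s too, closest to 0 in 600s_182s for junctions (−0.86) and contractile genes (−1.28). Of 17 basement membrane genes 15 were lower (−4.47, with Lamb1 at −5.66), of 21 interstitial matrix genes 18 (−3.96, −4.92 to −2.93, and −3.32 and −4.44 within 600s_182s and 613s), with Prelp at −5.83 and Bgn at 0.36, and of 14 contractile genes 12 (−3.44, with Tpm2 at −4.91). None of these 3 lists had a higher member after pooling, but the interstitial matrix had 1 within 600s_182s. With cells mixed at 20 CPM left out it had 2, and its median was −2.14 (−3.57 to 0.51). The intervals of the Wnt and junction medians below also include 0. Channels had 1 higher and 8 lower of 9 (−3.44, with Ednrb at −3.96), transporters 2 and 16 of 22 (−4.01, with Slco1c1 at −6.11), and retinoid handling 0 and 9 of 9 (−3.52). BMP and TGF-beta genes had 1 higher and 12 lower of 14 (−3.42, with Id1 at −5.35), Wnt genes 1 and 5 of 6 (−3.65, with Wnt5a at −4.83), and cytokines 1 and 23 of 25 (−4.05, with Cxcl12 at −6.55 and Il33 at −5.80). Junctions had 1 and 8 of 14 (−1.71, with F11r at −5.37), and stress genes 0 and 15 of 17 (−4.29, with Socs3 at −5.82 and Egr1 at −5.58). Proliferation genes were lower in 9 of 10 cases (−2.80, with Top2a at −3.45, Mki67 at −3.36 and Pcna at 0.23). Within 600s_182s 10 were lower (−3.79), but within 613s only 1 (−1.96). The remaining cells include the cycling cluster 11, with 15 of its 17 cells from 600s_182s.

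Oligodendrocyte-like cells were set against the 648 remaining cells, and were higher for Synpr, Galnt6, Tnni1 and Adamtsl4, each by a log2 ratio of at least 4.74. Galnt6, a glycosyltransferase (chromosome 15, 100691813 to 100729376, minus strand), had 494 CPM (490 to 499) against 14.7, with reads in 85.2% against 28.9% of thinned cells and a log2 ratio of 4.98 (4.34, 5.07 and 5.35 within 1025s_182s, 600s_182s and 613s). Synpr, a vesicle protein gene, stood at 5.15 (238 against 5.73 CPM), the troponin gene Tnni1 at 4.87, Adamtsl4 at 4.74, Rasal1 at 4.51, the contactin Cntn2 at 4.47, the receptor Gpr37 at 4.45 and the myelin gene Opalin, a naming marker, at 4.26. Within the lists, Ppp1r14a (3.60), the cytokine Il33 (2.54, 928 against 159 CPM), Csrp1 (2.48), the tight junction claudin Cldn11 (2.21, 3564 against 768 CPM), Smad7 (1.68), Jam3 (1.66) and Fgf1 (1.54) were higher. Pdgfra (−4.98) and Pdgfrb (−5.50) were lower. Tagln stood at −3.56, but at 0.13 within 600s_182s and at 0.50 with mixed cells left out.

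As for COP-like cells, all 12 list medians were below 0, at the 0.53 percentile or lower, and 11 of them were so within every set, with junctions at −1.11 and contractile genes at −1.74 within 600s_182s. Basement membrane genes were lower in 17 of 17 cases (−4.13, with Col18a1 at −5.72) and interstitial matrix genes in 22 of 23 (−4.62, and −5.94, −3.68 and −4.57 within the sets), with Prelp at −5.73 and Sparc at −2.52. Contractile genes had 2 higher and 12 lower of 15 (−3.48, with Tpm2 at −4.39 and Myl9 at −4.27), channels 0 and 10 of 10 (−3.64, with Ednra at −4.64), transporters 0 and 21 of 23 (−3.54, with Slco1a4 at −5.61) and retinoid handling 0 and 9 of 9 (−3.51, with Dhrs3 at −5.11). BMP and TGF-beta genes had 1 and 13 of 14 (−3.83, with Bmp7 at −5.65 and Bmp4 at −5.41), Wnt genes 0 and 7 of 7 (−4.03, with Wnt5a at −4.95), cytokines 3 and 21 of 26 (−4.12, with Igfbp3 at −5.38) and junctions 3 and 10 of 15 (−2.49, with Ocln at −4.79). Stress genes were lower in 14 of 17 cases (−1.96, with Cyr61 at −4.57 and Jund at 0.00). Proliferation genes were lower in 9 of 11 (−3.48, with Ccnb1 at −3.86 and Pcna at 0.36), but the median was 0.68 within 613s and 0.56 without set 600s_182s.

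The 102 fibroblast-like cells divided into sub-cluster 1 (41 cells), sub-cluster 2 (31 cells) and sub-cluster 3 (30 cells), each compared with the other fibroblast-like cells. In sub-cluster 2, Slc6a13, a transporter of GABA and taurine and a naming marker of fibroblasts (chromosome 6, 121300227 to 121337733, plus strand), had 2462 against 1.55 CPM, with reads in 93.5% against 9.86% of thinned cells and a log2 ratio of 9.92. The organic anion transporter Slc22a6 had 1049 CPM, with reads in 58.1% of cells, against 2 reads in the other cells. Without the added 1 CPM its ratio was 12555 (3474 to 103695). That value rests on the 2 reads and is not on the log2 scale of the other genes. Vitronectin (Vtn, chromosome 11, 78499091 to 78502324, plus strand), an adhesion protein and a pericyte marker, had 2786 CPM (2744 to 2828) against 13.2, in 96.8% against 22.5% of cells, a ratio of 7.61. Fam180a (9.26), the amino acid transporter Slc6a20a (9.03), Clec3b (7.65), Fbln2 (6.41) and Bmp7 (6.38) were also higher, as was the growth factor Igf2 (5.16, 2600 against 71.6 CPM).

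The sub-cluster came mostly from 600s_182s (23 cells), with 7 from 1025s_182s and 1 from 613s, so only 1025s_182s, with 7 cells against 42, gave values within a set. There Vtn stood at 7.79, Fbln2 at 8.21, Bmp7 at 6.40, Igf2 at 4.75 and Col15a1 at 3.44. Its median depth was 150980 reads, against 406557 in sub-cluster 1 and 158314 in sub-cluster 3.

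Of 17 basement membrane genes 12 were higher in sub-cluster 2 and 1 was lower (median 1.51, and 0.95 within 1025s_182s), with the collagens Col15a1 at 4.86 and Col4a6 at 4.74 and Agrn at −1.26. Of 26 transporters 13 were higher and 9 lower (0.82, −2.11 to 2.72, and 1.43 within the set; 0.41 with all list members), so transporters went both ways. The percentile of the basement membrane median (0.00 to 3.01) was 99.98 and that of transporters 99.83. Of 12 retinoid genes 2 were higher, Aldh1a2 (5.06) and Aldh1a1 (4.71), which make retinoic acid, and 8 lower (−2.95, −3.01 within 1025s_182s, and −3.15 with the member without reads at its bound). Of 16 BMP and TGF-beta genes 4 were higher and 9 lower (−1.79, but −4.72 within 1025s_182s, with 2 higher and 13 lower), with the transcriptional inhibitor Id2 at −6.61, and Gdf10 had 0 reads against 146 CPM, at least 294-fold lower with a floor of 3 counts over the class. Of 12 Wnt genes 7 were higher and 4 lower (1.10, but −1.78 within 1025s_182s), with Dkk3 at −3.26.

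Interstitial matrix genes had 6 higher and 6 lower of 24 (0.44, and 0.20 within 1025s_182s) in sub-cluster 2, with the proteoglycan Fmod at 7.01 in 32.3% of cells, Col8a1 at −6.89 and fibronectin (Fn1) at −3.09. Contractile genes had 0 and 6 of 14 (−0.83, and −4.44 within 1025s_182s), with Mylk at −6.03, and channels 4 and 4 of 13 (−0.31 and −1.17), with Ednra at −5.25. Cytokines had 6 and 11 of 28 (−0.37, and −2.70 within the set) and junctions 4 and 5 of 16 (−0.25, but −2.04 within the set), with the connexin Gja1 at 2.83, F11r at −4.89 and the cadherin Cdh11 at −6.28 (9.59 against 823 CPM, in 38.7% against 93.0% of cells). Stress genes had 2 and 9 of 18 (−1.11 and −1.75), with Hspa1a at 1.47 and Nr4a1 at −4.84, and proliferation genes 1 and 1 of 3 (−0.33, but 0.75 within the set). Among the layer lists, 4 of 6 arachnoid genes were higher and 1 lower (3.35, and 4.54 within 1025s_182s), with Angptl2 at 0.84, and 3 of 5 pial genes were higher and 0 lower (3.01, and 0.68 within the set). The pial genes S100a6 and Ngfr stood at 3.18 and 4.49, with Ngfr at −2.97 within 1025s_182s, and Lamc3 at −0.10. The perivascular list had 2 and 2 of 6 (−0.19, but 0.39 within the set), with Spp1 at 1.86, the arachnoid barrier list 1 and 1 of 4 (−0.32, but −4.62 within the set), with Abcg2 at −2.55, and the dura list 1 and 3 of 5 (−2.50 and −3.14), with Fxyd5 at −3.48. Only the intervals of the basement membrane (barely), contractile, retinoid, cytokine and stress medians leave out 0, among lists of over 5 members. Pdgfra was at 1.15, Pdgfrb at 0.30 and Tagln at −0.65.

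Sub-cluster 1 held 19 cells of 1025s_182s, 1 of 600s_182s and 21 of 613s. It was higher for the endothelin receptor Ednra (chromosome 8, 77663031 to 77724464, minus strand), with 158 CPM (153 to 164) against 11.5, in 53.7% against 14.8% of thinned cells, a log2 ratio of 3.67 (3.11 within 1025s_182s, 3.18 within 613s). The palmitoyltransferase Zdhhc6 stood at 3.29, the protease Zmpste24 at 2.82, Snapin at 2.71, Ccdc47 at 2.69 and the ectoenzyme Cd38 at 2.25. The glucose transporter Slc2a1 (2.67, and 4.41 and 0.59 within the sets) and the endothelial marker Cldn5 (2.29, 4.26 and 1.10) were also higher, and Slc2a1 was at −0.42 when cells needed 100000 reads. Wnt2 was higher (4.42, and 3.12 and 7.40 within the sets), as were Dkk3 (2.15), Mfap4 (1.75) and the matricellular gene Postn (1.66). Slc6a20a (−8.36), Bmp7 (−7.98) and Col15a1 (−3.74, but −1.44 and 0.55 within the sets) were lower overall. Pdgfra was at −0.88, Pdgfrb at −0.35 and Tagln at 0.51.

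In sub-cluster 1, basement membrane genes had 0 higher and 9 lower of 17 (−1.33, and −0.42 and 0.31 within 1025s_182s and 613s, the order used below) and transporters 5 and 14 of 25 (−1.59, −1.20 and −0.85). Contractile genes had 6 and 0 of 14 (0.75, 1.32 and −0.03), interstitial matrix genes 2 and 6 of 24 (−0.06, −0.21 and 0.66), channels 5 and 1 of 11 (0.56, −0.58 and 2.72), retinoid handling 4 and 3 of 12 (0.57, 0.35 and 0.64) and BMP and TGF-beta genes 4 and 6 of 17 (0.66, 0.25 within 1025s_182s and higher than both within 613s). Wnt genes had 2 and 4 of 11 (−0.85, −0.47 and 1.92), cytokines 6 and 9 of 29 (−0.20, 0.21 and 0.38), junctions 4 and 4 of 17 (0.10, −0.27 and −0.41), stress genes 1 and 1 of 18 (−0.03, −0.04 and 0.58) and proliferation genes 1 and 0 of 3 (0.09, 0.26 and 2.17). Of the layers, arachnoid genes had 0 and 5 of 6 (−3.64, −3.77 and −3.43), pial genes 0 and 3 of 5 (−1.70, −0.43 and 0.52), perivascular genes 0 and 1 of 6 (0.01, −0.18 and 0.48), arachnoid barrier genes 1 and 2 of 5 (0.29, −0.24 and −0.29) and dural genes 0 and 2 of 5 (−0.66, −0.32 and 0.77). Only the arachnoid, transporter, retinoid, BMP and TGF-beta and proliferation medians kept their sign within both sets, and only the basement membrane interval (−1.87 to −0.17) leaves out 0, among lists of over 5 members. That interval included 0 when clustering used all genes, at both other resolutions and with 10 principal components.

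Sub-cluster 3, with 23 cells of 1025s_182s, 1 of 600s_182s and 6 of 613s, had Car14, a membrane carbonic anhydrase, at 98.4 CPM (90.5 to 107) against 8.20, a log2 ratio of 3.43 (3.34 within 1025s_182s, 1.99 within 613s). Tmcc1 stood at 2.70, the nuclear receptor Nr4a1, an immediate early gene, at 2.31 (2.32 and 0.74), the histone demethylase Kdm6b at 2.17, Ccnl1 at 2.00, Wdr86 at 1.98, the kinase Ikbkb at 1.90 and Dach1 at 1.88. Dach1 was at −0.25 when cells needed 100000 reads. The collagen Col14a1 (1.68, but −0.22 with all genes used for clustering) and Klf4 (1.67) were higher, and Lama1 (−4.41) and Slc6a20a (−6.37) lower. Pdgfra (−0.06), Tagln (−0.17) and Pdgfrb (0.22) were within 2-fold.

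In sub-cluster 3, stress genes had 4 higher and 1 lower of 17 (0.47, −0.05 to 0.82, and 0.43 within both 1025s_182s and 613s, at the 99.56 percentile). Basement membrane genes had 0 and 6 of 17 (−0.72, −0.35 and −0.56) and interstitial matrix genes 5 and 8 of 24 (−0.47, −0.39 and −1.28). Their percentiles were 0.05 and 0.68, and that of the arachnoid list below was 0.01. Contractile genes had 0 and 5 of 14 (−0.21, −0.81 and 0.10), channels 0 and 4 of 8 (−0.72, −0.93 and −2.45), transporters 6 and 12 of 25 (−0.53, −0.51 and −0.72), retinoid handling 2 and 3 of 12 (−0.50, −0.04 and −0.60) and BMP and TGF-beta genes 2 and 3 of 16 (0.28, 0.07 and −1.27). Wnt genes had 3 and 5 of 11 (−0.27, 0.37 and −2.75), cytokines 7 and 8 of 29 (0.10, 0.04 and −0.02), junctions 4 and 3 of 17 (0.13, −0.24 and −0.68) and proliferation genes 0 and 2 of 3 (−2.90, −2.73 and −1.36). Of the layers, arachnoid genes had 1 and 4 of 6 (−2.84, −2.75 and −4.69), pial genes 0 and 3 of 5 (−1.15, −3.16 and −1.51), perivascular genes 0 and 2 of 6 (−0.17, −0.33 and −0.30), arachnoid barrier genes 1 and 1 of 5 (0.64, 0.88 and −2.24) and dural genes 1 and 0 of 5 (0.59, 0.79 and 0.45). The values within 613s rest on 6 cells, and the interval of every list of over 5 members includes 0.

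**Figure D3:**
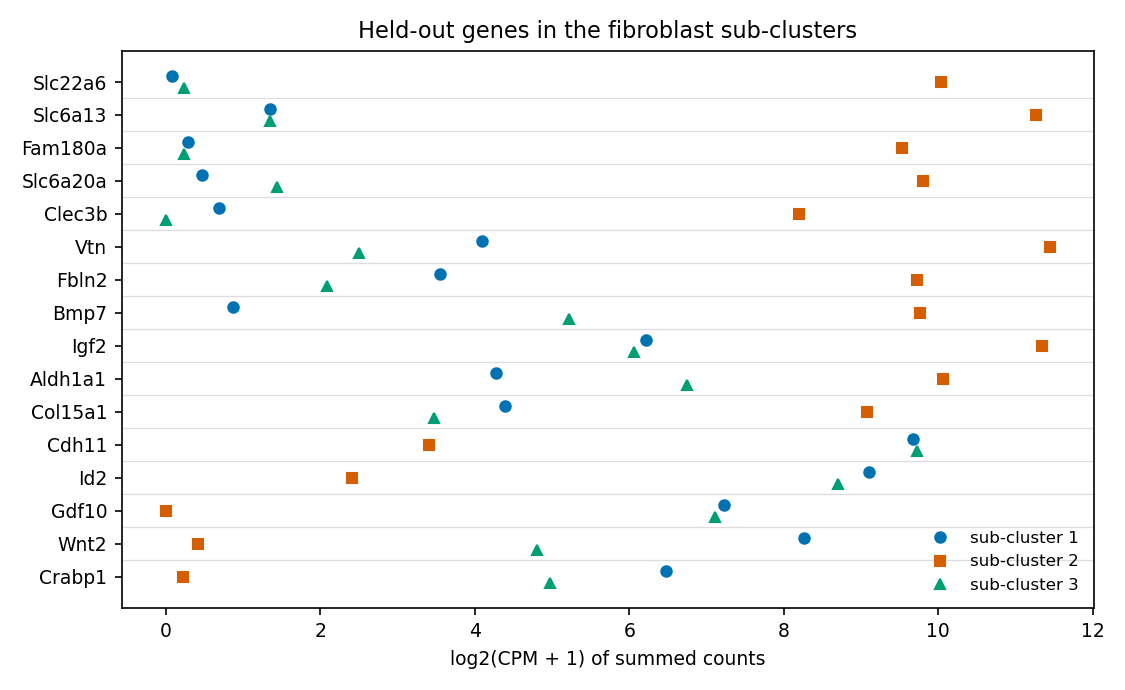
Points give log2(CPM + 1) of summed counts (horizontal axis) for 16 genes held out of the clustering (vertical axis) in fibroblast sub-clusters 1, 2 and 3. Vtn, at 2786 CPM in sub-cluster 2, and Igf2, at 2600 CPM, stand highest there, while Cdh11 is at 9.59 CPM.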

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

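In this part, the tests of depth and of pericyte RNA, the count of free RNA in oligodendrocyte-like cells, the test of the set difference of sub-cluster 2 and the mitochondrial comparisons of clusters 3 and 9 with named classes at like depth were chosen only after the results they measure were seen. The other tests with set bounds were fixed before their results were seen. For the nuclear RNAs of clusters 3 and 9 the fixed rule used only their median, and by that rule alone the result counts against RNA without nuclei. The reading by single genes, which leaves it open, was not part of the fixed rule. Mouse line and animal are biological differences of the design, but the labels tie neither to a well, so they stay open and no biological explanation was tested.

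The 295 wells left out for low depth held reads that no comparison above uses. Mbp, the gene of myelin basic protein (chromosome 18, 82475146 to 82585637, plus strand), stood at 16401 CPM in them, which does not tell RNA of cells from free RNA. In 1025s_182s (145 wells), 600s_182s (35) and 613s (115) it was at 23059, 5504 and 14096. Malat1 was at 7579 CPM over all (5092, 9693 and 9107 in these sets), Pdgfra at 122 (25.4, 404 and 113, with 456 of 905 reads from 600s_182s) and Tagln at 57.7 (93.9, 3.55 and 43.5), and mitochondrial genes took 13.1% of the reads (15.7%, 5.67% and 13.1%), so the pooled values depend on the set.

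The OPC-like and oligodendrocyte-like cells of set 600s_182s formed their own clusters, with 121 genes at least 4-fold apart from the other sets in OPC-like cells (63 higher, 58 lower) and 56 in oligodendrocyte-like cells (31 and 25). Depth stays open for OPC-like cells: with the 556 cells of at least 200000 reads thinned to that depth and clustered anew, 10.3% (2.87 to 24.2) of 39 cells of cluster 8 lay outside the cluster of most cells of cluster 1, against 97.4% without thinning, while 96.1% (86.5 to 99.5) of 51 cells of cluster 7 stayed apart from cluster 2, and at 50000 reads both pairs nearly merged (80.3% and 80.4% of their cells lay with the larger part of a new cluster, where full merging gives 77.3% and 72.2%). Free RNA of the kind in clusters 3 and 9 cannot be the whole source, as 21 of the 121 genes (17.4%, 11.1 to 25.3) and 17 of the 56 (30.4%, 18.8 to 44.1; 12 with oligodendrocyte-like cells as the reference) had the direction and the excess it needs, though these are 21 of the 58 and 17 of the 25 lower genes. A difference of the set shared by its cell types stays open. Between OPC-like and oligodendrocyte-like cells r was 0.293 across 2800 genes, which are not independent replicates. This lay between the bounds set for and against it, while 12 of 13 genes 2-fold apart in both classes had the same sign. Between OPC-like and fibroblast-like cells r was 0.138 across 1773 genes, a pair for which no bound was set. Of the 25 fibroblast-like cells of 600s_182s, 23 lay in sub-cluster 2, so that value also compares different fibroblasts. Set, animal and mouse line cannot be told apart here, since the labels tie no well to an animal or a line.

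Clusters 3 and 9 held shallow cells with mitochondrial shares of 7.47% and 9.08%, against 1.09% to 2.59% in the other classes. Shallow depth may account for part of this, as cells of named classes with under 93291 reads had a median share of 5.71% (quartiles 3.27 and 9.38, 40 cells), against 1.60% in deeper ones. At like depth the 2 clusters still lay higher. Under 93291 reads they had 11.8% (quartiles 10.0 and 13.6, 77 cells), a lower quartile 0.652 points above the upper quartile of named classes. At 100000 to 200000 reads their lower quartile (6.65%, 39 cells) lay 3.31 points above the upper quartile of named classes (3.34%, 114 cells). The sets were not held alike in this comparison, as only 1 cell of cluster 3 and 0 of cluster 9 came from 600s_182s. Mitochondrial genes were also not barred from the clustering that formed these clusters. Whether depth suffices therefore stays open. Pieces of cells or free RNA without nuclei stay open: the median log2 ratio of 4 nuclear RNAs over the remaining cells was 0.41, above the bound set against it, but Tug1 at −1.70 lay far from Malat1 (0.43), Neat1 (0.66) and Kcnq1ot1 (0.38), so the median is within their spread, and the clusters differ: Malat1 and Kcnq1ot1 were at 3784 and 91.4 CPM in cluster 3 but at 1834 and 45.9 in cluster 9, above and below the 2350 and 58.6 of the remaining cells, and Tug1 was at 35.6 and 6.41 against 87.5. Neat1 was higher in both clusters 3 and 9, at 129 and 164 CPM against 87.9. Mbp (14904 against 2849 CPM), Mobp (9173 against 1963) and the neuronal genes Camk2a, Ddn and Kif5a (log2 ratios 3.88, 4.68 and 3.90) were higher in these clusters, and the myelin genes Mog (−1.21) and Mag (−1.30) lower.

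Fibroblast sub-cluster 2 took most of its cells from set 600s_182s. RNA of pericytes is argued against as the source of its Vtn (2786 against 576 CPM in cluster 5), since relative to cluster 5 the highest of 6 other pericyte markers lay at −1.98 from Vtn on the log2 scale, with Rgs5 at 25.8 against 830 CPM and Higd1b at 11.6 against 111. Kcnj8 (68.6 against 55.8), Abcc9 (39.5 against 44.3), Atp13a5 (67.1 against 77.3) and Ndufa4l2 (128 against 135) were near the level of cluster 5, so some pericyte RNA stays open. A difference of the set stays open: of 398 genes at least 4-fold higher in its 600s_182s cells than in other fibroblast-like cells of 613s, 132 (33.2%, 28.6 to 38.0) were at least 2-fold higher within 1025s_182s, above 16.9% of 1192 genes that were within 2-fold, but between the bounds set for and against it. Of 649 lower genes 468 (72.1%) were lower there too, from 7 cells against 42, but no share of other genes was taken beside this value. Median log2 ratios within 1025s_182s were −0.34 for the 398 higher genes, −0.45 for the genes within 2-fold and −4.06 for the lower genes.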

How the results depend on the processing

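Leaving out cells mixed at 200 CPM, the cycling cluster, set 600s_182s or clusters 3 and 9 was chosen after seeing the data, as was applying the alternatives to single genes, and the other alternatives were planned. Where cells were clustered anew, each new cluster took the class that most of its cells had in the main result, without a check of markers. By this step oligodendrocyte-like cells numbered 261 with 100000 reads required, against 209 in the main result. The cause of the changes below was not tested otherwise, except that leaving out cells or sets changes shares by construction. With 100000 reads and 1500 genes required, oligodendrocyte-like cells were 36.2% and the lineage 79.5%, the interstitial matrix median of oligodendrocyte-like cells was −3.40, Slc2a1 in sub-cluster 1 was −0.42 and Dach1 in sub-cluster 3 −0.25. With 20000 reads and 500 genes, OPC-like cells were 25.3%, oligodendrocyte-like 19.2% and the lineage 51.8%. Clustering on all genes gave 16.5% oligodendrocyte-like, 55.1% lineage and −0.22 for Col14a1 in sub-cluster 3. Resolution 0.3 gave 16.0% COP-like, 27.4% oligodendrocyte-like and 72.8% lineage, and 30 components 24.6% OPC-like and 58.9% lineage. Without cells mixed at 20 CPM the shares were 38.5% OPC-like, 16.6% COP-like, 36.7% oligodendrocyte-like, 91.8% lineage and 2.30% fibroblast-like. The interstitial matrix medians were then −2.14 for COP-like and −3.29 for oligodendrocyte-like cells, and Tagln in the latter 0.50. A pseudocount of 0.1 gave −5.38 for the oligodendrocyte-like interstitial matrix median, and one of 5 gave −2.66 for COP-like and −3.32 for oligodendrocyte-like cells. Without cells mixed at 200 CPM the 5 shares, in the order above, were 33.5%, 11.7%, 29.1%, 74.3% and 8.01%. Without set 600s_182s they were 11.2%, 2.36%, 30.3%, 43.9% and 15.2%, Fbln2 in fibroblast-like cells was −0.13, and in oligodendrocyte-like cells the interstitial matrix median was −5.19 and the proliferation median 0.56. Without clusters 3 and 9, OPC-like cells were 34.9%, oligodendrocyte-like 29.1% and the lineage 75.0%.

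Of 1406 alternative list medians 1202 counted as the same, 203 as moved and 1 as reversed. A median moved when it left the interval of the main value. Lists with no more than 5 measured members have no interval, and for them any change counted as a move. Of 3043 alternative log2 ratios of named genes 326 were unchanged, 2712 moved by any amount, and 5 changed sign in genes called higher or lower. These moves were not set against counting error. Of 394 shares of cells with reads, 279 moved without thinning, all higher, and 319 with 5 reads required, all lower, 60 of them to 0% (median changes over all 394 of 14.0 and −12.9 points). Medians changed sign in 1 of 624 cases for the classes and in 62 of 782 for the sub-clusters, and gene ratios in 20 of 2067 and 24 of 976. The fibroblast-like over OPC-like interstitial matrix median ranged from 4.20 to 6.41, within its interval in 17 of 17 alternatives. The sub-cluster medians ranged from −1.64 to −0.49 (basement membrane, sub-cluster 1), 0.41 to 1.89 (transporters, sub-cluster 2) and −1.39 to −0.28 (basement membrane, sub-cluster 3). No value could be had, for want of 20 cells, for COP-like cells without set 600s_182s, for fibroblast-like against OPC-like cells without cells mixed at 20 CPM, for sub-clusters 1 and 2 under both exclusions of mixed cells, for sub-cluster 2 with 100000 reads or without 600s_182s, and for sub-cluster 3 without cells mixed at 20 CPM. At the lower resolution no sub-cluster 3 formed. The sub-clusters rest on 30 to 41 cells each. No paired analysis was possible because the labels name no replicates and the series is 1 sample.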

Other observations

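The count of cycling cells and the values of Ttr were chosen only after the results were seen, and the count of sex-linked reads was planned.

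Cycling cells were found in the OPC-like class. At least 5 proliferation genes at 20 CPM were present in 23 of 250 OPC-like cells (9.20%, 5.92 to 13.5), by set in 1 of 20 of 1025s_182s, 19 of 193 of 600s_182s (9.84%) and 3 of 37 of 613s (8.11%), and in 0 of the cells of every other class and unnamed cluster, with upper interval bounds of 1.75% in oligodendrocyte-like, 3.55% in fibroblast-like, 4.56% in COP-like and 23.2% in choroid plexus epithelium-like cells, and 4.15%, 5.69% and 6.72% in clusters 3, 5 and 9. The bounds of cluster 9 and of the choroid plexus cells exceed the lower bound of OPC-like cells. The 14 choroid plexus epithelium-like cells came from 1025s_182s (7) and 613s (7). Ttr, the transthyretin gene of that epithelium, was at 254 CPM in OPC-like cells of these sets against 10.2 CPM in those of 600s_182s, and at 157 against 2.04 CPM in oligodendrocyte-like cells.

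Reads of the sex-linked genes were counted as a check for mixed wells. Xist had reads in 31 cells, 7 of them with at least 10, and Y-linked genes in 781 cells, 517 of them with at least 10. Both kinds were found in 31 cells, 3 of them with at least 10 reads of each. Of 556 cells with at least 200000 reads, 31 had no Y-linked read, 28 of these in 1025s_182s, and 0 of them had a read of Xist. Xist overlaps the antisense gene Tsix, and the strand setting of the counting is not given, so the counts of Xist do not assign a sex to a cell. The Y-linked genes lie outside that overlap. They had reads in 175 of 239 cells of 1025s_182s, 344 of 349 of 600s_182s and 262 of 269 of 613s. No cell had reads of Xist alone. Because the counts of Xist do not assign a sex, this does not show that cells of females were absent, and the labels name both sexes. The 31 cells of at least 200000 reads without a Y-linked read were not assigned to a sex. Stray reads between wells were not tested as a source of the sex-linked reads.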
